A study of Mus musculus with 8 samples.

How the data were processed

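Total RNA of 8 sorted mouse cell samples, 2 biological replicates each of naive CD4 T cells, naive CD8 T cells, plasmacytoid dendritic cells (pDC) and peritoneal B cells, was sequenced. RNA was isolated with a column kit and libraries were made with Illumina protocols, per the labels' protocols. The labels do not say whether the replicates came from separate animals or pools, or whether library preparation marked strand. The submitters' processing notes name Subread, featureCounts and limma without versions and the genome builds GRCm38 and mm10. They do not state the strand setting or the handling of reads with several matches, so reads of near-identical or overlapping genes are uncertain. The authors deposited a table of raw counts per Entrez gene, without normalization per the file headers, for 27179 genes, 26324 of them with a symbol. The authors also deposited log2 RPKM values per library, per the file headers. Checked on the values, these hold 15655 of the genes, leave out 855 genes without a symbol, 2687 with symbols starting Gm (17 of which have a letter next, such as Gmfb) and 7982 with another symbol (at most 17 counts in a library, rRNA genes apart), and look quantile normalized: in 232 of 232 cases a gene at the same count rank in 2 libraries, with at least 100 counts, had the same log2 RPKM within 0.01. No step that gave them is recorded in the labels. Coordinates are those of the RefSeq annotation of GRCm38.p6, matched by gene ID for 25275 genes.

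The tests used the deposited counts. Genes passed edgeR's filterByExpr by group (minimum count 10, minimum total 15), which left 13946, and libraries were scaled by TMM (factors 0.9554 to 1.041). A gene absent from some groups could pass only through the others. Where this holds for most genes of a list or family, the share called higher is partly set by the filter. All 8 libraries of the 4 groups were fitted together by edgeR's quasi-likelihood method with group as the model, so that they shared 1 estimate of spread, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. The contrasts were pDC against the mean of the log values of the 3 lymphocyte groups, its 3 pairwise parts, peritoneal B against the mean of the T cell groups, and naive CD8 T against naive CD4 T. A gene can be called higher than a mean of groups while lower than 1 of them. Log2 fold changes, SE and adjusted p-values are those of the comparison described, unless a pairwise part is named. This holds also where they stand beside a fold or level of 1 group. Genes called the same way in all 3 pairwise parts were counted, beside the overlap of independent lists and of 20 simulations with unchanged groups. Levels are CPM from TMM-scaled library sizes, as mean ± SD of 2 libraries, and log CPM used a prior count of 2. An SE was not fitted directly. It is the absolute log2 fold change, without the prior count, over the square root of the test's F statistic. Where a group has few counts, such as Sidt1 in pDC or Zbtb7b in naive CD8 T, it can understate the error. Total counts per library ran from 14102557 to 23017140. Where a group had no count, a fold is a lower bound taken against 3 counts over the group. Reads have no molecular identifiers, so such limits cover counting error only. Where a group had 1 to 3 counts, levels are given in place of a fold. The 10 highest genes took 5.193% to 6.164% of the counts and genes without a symbol 0.1803% to 0.2931%.

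Gene lists were written from general knowledge of these cells before the data were examined, as were the design, the rule for naming genes and most of the alternatives. Of 25 lists, 1 holds the genes of the sorts and 1 the focus genes Cxcl10, Cxcr3, Tlr7, Tlr9 and Irf7. The other 23 were tested in 3 comparisons: identity genes of pDC, B cells and T cells, the CD8 and CD4 lineages, regulatory T cells, conventional dendritic cells, macrophages and monocytes, neutrophils, natural killer cells, erythroid cells, platelets, plasma cells, B-1 cells, endosomal Toll-like receptors and their pathway, other pattern recognition receptors, interferon-stimulated genes, cytokines and chemokines, chemokine receptors, MHC class II presentation, the endoplasmic reticulum and secretion, cell cycle and immediate early genes. Some genes are in several lists. Each was tested with camera at a preset correlation of 0.01 and with an estimated one, adjusted over the 69 pairs of list and comparison. Camera compares a list with the other genes. Fry's directional p-value tests whether a list's genes move on balance one way and its mixed p-value whether they change in either direction, and neither compares with other genes.

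The genes named follow a rule. They are the genes of the sorts, the 6 called genes with the highest and the 6 with the lowest log2 fold change per comparison, up to 4 called genes per list with the largest change, the list genes called against the direction of most of the list, up to 2 genes of the highest level where fewer than 2 were called, the focus genes, and for lists of other cell types the gene with the highest level in the group they could have entered. The 6 at each end had at least 20 CPM on the higher side, no overlap between the libraries of both sides, the same direction in each pairwise part, and were not immunoglobulin or T cell receptor genes. Not every gene of the rule is printed. Cd72, given as the B cell identity gene that did not pass, was chosen after its values were seen.

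The test was run on data simulated with the sizes of these libraries and, in every group, each gene's mean over all 8 libraries. In each of 10 simulations, 200 genes above a minimum mean level were changed. For pDC against lymphocytes the test recovered 69% of genes changed 1.5-fold, 85.5% of those changed 2-fold and 97.3% of those changed 4-fold. Of its calls 8.66% were false, above the nominal 5%. In the data 9978 of 13946 genes were called there, so these shares need not hold for the reported calls or for low counts. Alternatives were DESeq2 size factors in edgeR, library size alone, no filter on low counts, a filter of 5 CPM in 2 libraries, DESeq2's own test, limma-voom, a test against a 2-fold change (glmTreat), limma-trend on the deposited log2 RPKM, the replicate number as a block, the groups compared alone, an adjusted p under 0.01, and leaving out each library in turn. The other deposited per-sample columns not used here numbered 0. Tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, and, for figures, Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.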

Results

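Gene expression was measured by RNA sequencing in 4 kinds of haematopoietic cell sorted from C57BL/6 mice aged 7 to 12 weeks. The title of the series concerns plasmacytoid dendritic cells (pDC), the chemokine CXCL10 and stimulation of the receptor TLR7, and its design text describes a comparison of cell types. The labels of the 8 libraries name no stimulation. There were 2 biological replicates of each type. The pDC, cells specialised in making type I interferon, were sorted from spleen as CD11c low and CD45RA high. Naive CD4 T cells were sorted from spleen and lymph nodes as CD4 positive, CD62L positive, CD25 negative and CD44 negative. Naive CD8 T cells came from the same tissues and were CD8 positive, CD62L positive and CD44 negative. Peritoneal B cells came from lavage and were positive for B220 and CD19 and negative for Ter119, F4/80 and Mac-1. The total count per library was 14102557 and 14419533 in naive CD4 T, 14503269 and 15361431 in naive CD8 T, 15633716 and 15434899 in pDC, and 23017140 and 22657941 in peritoneal B. Between 14820 and 16629 genes had a count in a library, and 13946 genes entered the tests. A gene with no count in a group was below 0.103 CPM in naive CD4 T, 0.0975 in naive CD8 T, 0.101 in pDC and 0.0666 in peritoneal B, taking 3 counts over the group as the limit, which covers counting error only.

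The libraries grouped by cell type. The first principal component held 67.9% of the variance and separated the T cells from pDC and peritoneal B. The second held 26.7% and separated pDC from peritoneal B. The third held 3.5% and separated naive CD8 T from naive CD4 T. Replicates had a Pearson r, across genes, of 0.9945 in naive CD4 T, 0.994 in naive CD8 T, 0.9936 in pDC and 0.9909 in peritoneal B. Genes are not independent replicates. Between types, r was lowest for pDC with T cells (0.7087 to 0.7181), higher for peritoneal B with T cells (0.7285 to 0.742) and for pDC with peritoneal B (0.7909 to 0.7937), and highest for naive CD4 T with naive CD8 T (0.9749 to 0.9756). As a measure of spread between replicates relative to counting, the mean chi-square per gene was 2.76 in pDC, 4.99 in naive CD4 T, 6.52 in naive CD8 T and 14.5 in peritoneal B. The median, relative to its value for counting alone, ranged less: 1.85, 2.44, 2.64 and 3.9 in the same order. Both grow with depth, which was highest in peritoneal B. The peritoneal B libraries have another identifier prefix than the other 6 libraries and came from another tissue, so prefix, tissue and cell type cannot be told apart for them.

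The genes of the proteins used in the sorts checked the labels. They are selection markers and not findings. Cd4 (chromosome 6, 124864693 to 124888247, GRCm38) had 1210 ± 3.87 CPM in naive CD4 T and 0.265 ± 0.199 in naive CD8 T (mean ± SD, n = 2, as for all levels given with ±). Cd8a (chromosome 6, 71373427 to 71379171) had 1730 ± 51.5 CPM in naive CD8 T and 0.513 ± 0.237 in naive CD4 T. Cd19 (chromosome 7, 126408448 to 126415148) had 1860 ± 168 CPM in peritoneal B and 6.6 ± 0.719 in pDC. Itgax, which encodes CD11c, had 974 ± 30.6 CPM in pDC and 1.85 ± 1.31 in peritoneal B. Sell, which encodes CD62L, had 1070 ± 25.4 CPM in naive CD4 T and 1350 ± 134 in naive CD8 T. Il2ra, which encodes CD25, had 4.99 ± 3.21 CPM in naive CD4 T. Cd44 had 59.2 ± 5.22 CPM in naive CD4 T and 8.45 ± 9.57 in naive CD8 T, where the libraries held 15.2 and 1.69. Ptprc, the gene of every CD45 form including CD45RA and B220, had 1450 ± 12.3 to 3190 ± 151 CPM, and gene counts do not separate its forms. Itgam (Mac-1) had 286 ± 20.6 CPM and Adgre1 (F4/80) 66.2 ± 5.07 in peritoneal B, although the sort excluded both proteins. The pDC libraries held Cd4 at 618 ± 23.9 CPM, Cd8a at 277 ± 3.35 and Cd8b1 at 185 ± 11.7.

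**Figure D1:**
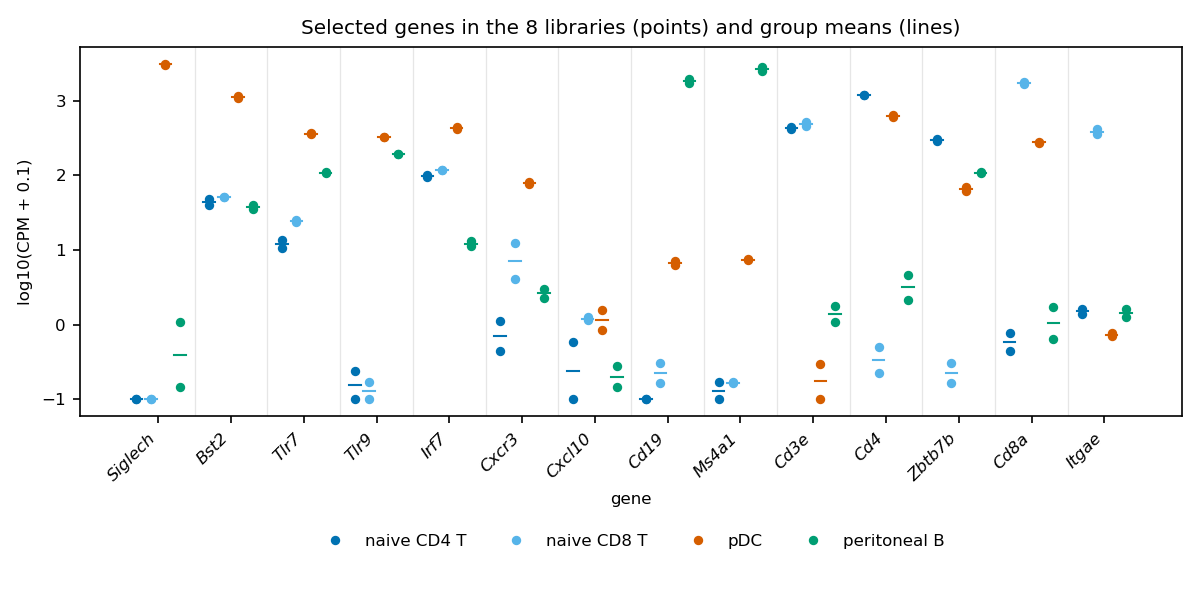
Level of 14 genes in each of the 8 libraries, as log10 of CPM plus 0.1 on the vertical axis; points are libraries, short lines are the means of the 2 libraries of a group. Siglech, Bst2, Tlr7, Irf7 and Cxcr3 were highest in pDC, while Cxcl10 stayed near 1 CPM or below in every library.

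The first comparison, pDC against the mean of the 3 lymphocyte groups, asked which genes set pDC apart. Siglech (chromosome 7, 55768154 to 55779448), a sialic acid-binding receptor, had 3080 ± 64.4 CPM in pDC, no count in T cells, and 0.0439 and 0.987 CPM in the peritoneal B libraries. It was at least 30000-fold higher than in naive CD4 T and at least 31600-fold higher than in naive CD8 T. Against the mean of the lymphocytes it was called higher (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 1.14e-10). Adam11, of the ADAM membrane proteins, had 769 ± 72.1 CPM in pDC and was at least 7480-fold higher than in naive CD4 T. It too was called higher against the mean (edgeR adjusted p = 2.71e-12). Clec9a (chromosome 6, 129408862 to 129424764), a receptor for dead cells, had 552 ± 31.4 CPM in pDC and was at least 5370-fold higher than in naive CD4 T, with 0.351 and 0.718 CPM in the peritoneal B libraries. Kdr (chromosome 5, 75932827 to 75979072), a receptor for vascular endothelial growth factor, had 188 ± 12.6 CPM in pDC and was at least 1820-fold higher than in naive CD4 T. Cd300c had 309 ± 13.8 CPM and Cd209d 417 ± 13.1 CPM in pDC, and neither had a count in T cells. Cd209d has close paralogs, so its reads are uncertain.

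The genes furthest below the lymphocytes included T cell genes. Cd3e (chromosome 9, 44998735 to 45009663), a chain of the T cell receptor complex, had 434 ± 16.6 CPM in naive CD4 T, 492 ± 37.7 in naive CD8 T and 0.1 ± 0.142 in pDC (edgeR adjusted p = 1.5e-09). Themis, a signalling protein of T cells, had 249 ± 2.94 and 343 ± 27.6 CPM in the T cells and 0.0335 ± 0.0474 in pDC. Tdrp, named for testis development, had no count in pDC and was at least 1300-fold lower than in naive CD4 T and at least 2220-fold lower than in naive CD8 T. A630023P12Rik, an uncharacterised gene, also had no count in pDC, at least 896-fold lower than in naive CD4 T, 332-fold lower than in naive CD8 T and 185-fold lower than in peritoneal B. Sidt1, of a family of RNA transporters, had 145 ± 2.06 CPM in naive CD4 T, 344 ± 57.2 in naive CD8 T and 0.168 ± 0.142 in pDC (log2 fold change -9.22, SE 0.27, edgeR adjusted p = 2.17e-10, -10.45 without pDC replicate 1 and -8.56 without pDC replicate 2). Ctla4, an inhibitory receptor, had 57 ± 19.7 CPM in peritoneal B and no count in pDC, which was at least 567-fold lower.

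The genes around CXCL10 and the nucleic acid sensors were of focus because of the title. Tlr7 (chromosome X, 167303380 to 167330574), a sensor of single-stranded RNA, had 362 ± 9.93 CPM in pDC, 109 ± 3.41 in peritoneal B, 24.3 ± 1.17 in naive CD8 T and 12 ± 2 in naive CD4 T (log2 fold change 3.52, SE 0.06, edgeR adjusted p = 3e-12). Tlr9 (chromosome 9, 106222598 to 106226876), a sensor of CpG DNA, had 329 ± 0.598 CPM in pDC and 193 ± 1.57 in peritoneal B, a log2 difference of 0.77 (edgeR adjusted p = 4.76e-06), and at most 0.0691 CPM in T cells. Its difference from peritoneal B was not called on the deposited log2 RPKM (0.72, limma-trend adjusted p = 0.332). Irf7 (chromosome 7, 141263183 to 141266499), a transcription factor of the interferon response, had 430 ± 20 CPM in pDC, 99 ± 3.69 in naive CD4 T, 118 ± 1.16 in naive CD8 T and 12.1 ± 1.39 in peritoneal B (log2 fold change 3.04, SE 0.05, edgeR adjusted p = 4.07e-12). Cxcr3 (chromosome X, 101731535 to 101734147), the receptor of CXCL10, had 78.4 ± 3.13 CPM in pDC and 8.09 ± 5.78 in naive CD8 T. Its log2 fold change was 5.02 against the mean of the lymphocytes (SE 0.27, edgeR adjusted p = 2.86e-08) and 3.29 against naive CD8 T. Cxcl10 (chromosome 5, 92346638 to 92348889) itself was near the limit of detection, with 22 and 11 counts in pDC, 17 and 17 in naive CD8 T, 7 and 0 in naive CD4 T and 4 and 1 in peritoneal B. Its mean was 1.11 ± 0.52 CPM in pDC and 1.11 ± 0.0614 in naive CD8 T, and no difference between these groups was detectable at this depth (edgeR adjusted p = 1). Against the mean of the lymphocytes Cxcl10 was called higher (log2 fold change 1.80, SE 0.61, edgeR adjusted p = 0.0196). Without pDC replicate 1 the call was lost (1.22, adjusted p = 0.272), without naive CD4 T replicate 1, which left that group with no count, it was kept (adjusted p = 0.00258), and it was lost with DESeq2 (adjusted p = 0.0793) and on the deposited log2 RPKM (adjusted p = 0.303).

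Lists of genes fixed beforehand were tested as sets with camera at a preset correlation between genes of 0.01. Counts of called members adjusted over the list alone were the same as those over all genes tested, except where both are given. None of the 69 pairs of list and comparison was called with an estimated correlation, where the smallest adjusted p was 0.179. Of the pDC identity list, 28 of 28 genes rose in pDC, among them Siglech, Cd209d, Cd300c and Klk1, a kallikrein protease with 392 ± 10.6 CPM (camera adjusted p = 2.98e-11, adjusted p = 0.179 with an estimated correlation). Of the T cell identity list, 22 of 24 genes fell and 1 rose (camera adjusted p = 8.16e-09, adjusted p = 0.432 with an estimated correlation). Bcl11b, a T lineage transcription factor, fell to 0.134 ± 0.095 CPM from 604 ± 13.2 in naive CD4 T. Il7r, the interleukin 7 receptor, was the gene that rose, and its 286 ± 31.6 CPM in pDC lay below the 707 ± 31.7 of naive CD4 T. Of the CD4 lineage list, 11 of 13 genes fell and 2 rose (camera adjusted p = 0.0013, adjusted p = 0.432 with an estimated correlation). Igfbp4, which binds insulin-like growth factors, fell to 0.637 ± 0.0482 CPM from 859 ± 30.8. Cd4 and Zbtb7b were called higher than the mean of the lymphocytes, but in pDC they were below naive CD4 T. The CD8 lineage list was not called, with 6 higher and 11 lower of 22 (camera adjusted p = 0.341), and 9 higher and 5 lower against peritoneal B alone. Klrd1, a receptor chain of cytotoxic cells with close relatives, had 249 ± 4.67 CPM in pDC and 192 ± 0.835 in naive CD8 T, while Il2rb and Crtam fell.

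Endosomal sensing, antigen presentation and secretion lists rose in pDC against the mean of the lymphocytes. Of the endosomal Toll-like receptor list, 17 of 20 genes rose and 2 fell (camera adjusted p = 9.62e-05, adjusted p = 0.322 with an estimated correlation). Pld4, a nuclease of endosomes, had 1390 ± 1.35 CPM in pDC and 546 ± 62.6 in peritoneal B, and Ctsl, a lysosomal protease, had 927 ± 3.07 CPM in pDC and at most 14.3 ± 0.31 elsewhere. Traf3 and Pld3 were the genes that fell, Pld3 to 13.6 ± 0.362 CPM from 210 ± 2.57 in naive CD8 T. Of the MHC class II list, 13 of 15 rose and 2 fell (camera adjusted p = 0.000288, adjusted p = 0.322 with an estimated correlation). Against peritoneal B alone 4 rose and 9 fell (median log2 fold change -0.479). H2-Aa, a class II chain, had 2860 ± 200 CPM in pDC, below the 3980 ± 127 of peritoneal B, and at most 0.385 ± 0.162 in T cells. H2-Ob and Cd86 fell, Cd86, a costimulatory protein, to 7.81 ± 1.18 CPM from 64.6 ± 6.85 in peritoneal B. Of the list of the endoplasmic reticulum and secretion, 27 of 30 rose and 1 fell (camera adjusted p = 4.07e-07, adjusted p = 0.397 with an estimated correlation). Ern1 and Xbp1, a sensor and a transcription factor of the unfolded protein response, had 155 ± 6.64 and 395 ± 19.1 CPM in pDC and at most 20.2 ± 0.671 and 88.1 ± 5.06 elsewhere. Edem1 was the gene that fell (log2 fold change -0.13, edgeR adjusted p = 0.0454), and its call was lost without naive CD4 T replicate 1, naive CD8 T replicate 1, pDC replicate 1 or pDC replicate 2 (-0.14 to -0.13), without peritoneal B replicate 2 (-0.11) and with DESeq2 or its size factors (-0.11). Of the plasma cell list, 6 of 7 rose, among them Sdc1 and Jchain, and Prdm1 fell to 0.57 ± 0.0467 CPM from 19.1 ± 0.0342 in peritoneal B (camera adjusted p = 0.0248, adjusted p = 0.398 with an estimated correlation). Compared with peritoneal B alone, 2 plasma cell genes rose and 3 fell.

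The interferon-stimulated list went both ways in pDC. Of its 34 genes 18 rose (19 adjusted over the list alone) and 11 fell, and the list was not called (camera adjusted p = 0.294). It had 14 higher and 15 lower against naive CD8 T and 24 higher and 7 lower against peritoneal B. Bst2 (chromosome 8, 71534255 to 71537472), a membrane protein that tethers viruses, had 1120 ± 66.2 CPM in pDC and at most 51.7 ± 0.118 elsewhere (log2 fold change 4.67, SE 0.06, edgeR adjusted p = 1.02e-12). Ifitm3, which blocks virus entry, had 118 ± 20.4 CPM in pDC and 14.3 ± 6.88 in peritoneal B. The genes that fell included Rtp4, Ifit1, Oas3 and Zbp1, a sensor of nucleic acids with 9.99 ± 0.177 CPM in pDC and 142 ± 6.33 in naive CD4 T. Of the list of other pattern recognition receptors, 12 of 21 rose and 4 fell (camera adjusted p = 0.181), and against peritoneal B 9 rose and 11 fell. Tlr5, a sensor of flagellin, had 21.2 ± 1.11 CPM in pDC, at least 206-fold higher than in naive CD4 T. Ddx58, a cytosolic RNA sensor, fell to 11.2 ± 2.31 CPM from 223 ± 14 in peritoneal B, as did Tlr1, Nod1 and Zbp1. Of the chemokine receptor list, 11 of 19 tested (of 20 listed) rose and 5 fell (camera adjusted p = 0.475), against peritoneal B 6 and 6, and on the deposited log2 RPKM 10 and 8 of 20. Ccr2 had 1010 ± 29.7 CPM in pDC and at most 12.5 ± 2.35 elsewhere. Ccr7, a receptor for entry to lymph nodes, fell to 5.3 ± 0.657 CPM from 500 ± 6.14 in naive CD4 T, and Cxcr5, Cxcr6, Cxcr4 and Ccr4 fell too. Of the cytokine and chemokine list, 10 of 18 tested (of 31 listed) rose and 5 fell (camera adjusted p = 0.555), against peritoneal B 7 and 8. Its median of 1.55 was -0.151 on the deposited log2 RPKM, where 9 of 27 rose and 7 fell. Cxcl9, a close relative of Cxcl10, had 1.81 ± 0.0971 CPM in pDC, at least 17.6-fold higher than in naive CD4 T. Ltb, Lta, Tnf, Tnfsf10 and Il16 fell, Ltb to 29 ± 1.17 CPM from 509 ± 29.9.

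Lists of other cell types showed which of their genes the pDC libraries held. Of the conventional dendritic cell list, 12 of 13 tested (of 15 listed) rose and Id2, a transcription factor, fell (camera adjusted p = 0.000278, adjusted p = 0.322 with an estimated correlation). Besides Clec9a and Itgax, Clec10a had 324 ± 1.64 CPM in pDC, and Cd209a, which has close paralogs, had 637 ± 7.65. Of the macrophage and monocyte list, 11 of 19 tested (of 20 listed) rose, led by Ccr2, and Csf1r had 188 ± 19.1 CPM and Cd68 326 ± 8.84 (camera adjusted p = 0.0393, adjusted p = 0.573 with an estimated correlation). That call was lost without pDC replicate 1 (adjusted p = 0.0589), without peritoneal B replicate 2 (adjusted p = 0.0507) and with the replicate number as a block (adjusted p = 0.0548). The list was higher than in T cells and mostly lower than in peritoneal B: 16 rose and none fell against each T cell group, and 4 rose and 15 fell against peritoneal B (median log2 fold change -3.53). The deposited log2 RPKM gave 8 higher and 1 lower of 20 against the mean. The regulatory T cell list (3 higher, 6 lower of 10, camera adjusted p = 0.454), the B cell identity list (15 higher, 6 lower of 23, camera adjusted p = 0.691) and the B-1 cell list (7 higher, 4 lower of 14, camera adjusted p = 0.865) were not called. Compared with peritoneal B alone, the B cell identity list had 1 higher and 22 lower and the B-1 cell list 4 and 9. Nrp1, a coreceptor of semaphorins, had 200 ± 3.31 CPM in pDC and at most 5.26 ± 0.11 elsewhere, and Fcrla, of the Fc receptor-like family, had 310 ± 4.26 CPM in pDC and 541 ± 37 in peritoneal B. The natural killer list (2 higher, 1 lower of 5 tested, camera adjusted p = 0.68) was led by Klri2 at 16.7 ± 2.02 CPM, and Prf1 fell. Vwf was the called gene of the platelet list (1 higher of 4 tested, camera adjusted p = 0.706, with a median log2 fold change of -0.48 and a mean of 0.07), and Gp1ba was its highest at 2.01 ± 0.472 CPM. Gp1ba was not called (log2 fold change -0.39), but was called lower on the deposited log2 RPKM (-0.88, limma-trend adjusted p = 0.0107), where 2 of 5 platelet genes rose and 3 fell.

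Among lists with few counts or replicate differences, 3 of 6 neutrophil genes tested (of 13 listed) rose (Csf3r, Mmp9 and Cxcr2, camera adjusted p = 0.341), with Csf3r highest at 3.12 ± 0.905 CPM. Against peritoneal B none rose and 5 fell. On the deposited log2 RPKM 1 of 13 rose, and the list's median of 2.56 was -0.189. Without pDC replicate 2 the number was 1 of 11, without peritoneal B replicate 1 it was 5 of 6, and without peritoneal B replicate 2 it was 5 of 11 with 1 lower. The call of Mmp9 was lost without naive CD4 T replicate 2 (log2 fold change 1.35 against 1.49), naive CD8 T replicate 1 (1.5), naive CD8 T replicate 2 (1.47) or pDC replicate 2 (0.69), and that of Cxcr2 without pDC replicate 2 (2.96 against 3.31), while Cxcr2 was at 4.15 without naive CD4 T replicate 2. Mmp9 was not called with DESeq2 (1.58), limma-voom (1.18) or the deposited log2 RPKM (0.66) either, nor was Cxcr2 with the last (1.66). Of the erythroid list, 3 of 4 rose (4 adjusted over the list alone, camera adjusted p = 0.341), and the highest was Hba-a2, an alpha globin gene with a near-identical copy, at 2.51 ± 0.24 CPM. Without naive CD4 T replicate 1, pDC replicate 1 or pDC replicate 2, 1 of 5 rose, and 1 of 7 on the deposited log2 RPKM. The call of Hba-a2 was lost without naive CD4 T replicate 1 (1.81 against 2.13), naive CD8 T replicate 2 (1.82), pDC replicate 1 (2.22) or pDC replicate 2 (2.03), and on the deposited log2 RPKM (2.35). It was kept without naive CD4 T replicate 2 (3.56), naive CD8 T replicate 1 (2.97) and peritoneal B replicate 1 (2.83). Of the cell cycle list, 1 of 27 rose (Aurkb, a mitotic kinase) and 9 fell, and it was not called (camera adjusted p = 0.559, towards lower, although its median was 0.128 and its mean 0.0712, and on the deposited log2 RPKM its median was -0.204). The pairwise parts ran apart, with 12 higher and 7 lower against naive CD4 T (median 1.12), 8 and 8 against naive CD8 T, and 0 and 24 against peritoneal B (median -1.77). With DESeq2 size factors 3 rose against the mean, and with the replicate number as a block 5 did. Without peritoneal B replicate 1 the count was 6 higher and 12 lower, and without peritoneal B replicate 2 it was 13 higher and 9 lower. Of the immediate early list, 6 of 22 rose and 12 fell (camera adjusted p = 0.277). Klf4, a transcription factor, had 348 ± 20 CPM in pDC and at most 22 ± 3.72 elsewhere, while Egr1, another, fell to 2.61 ± 0.288 CPM from 91.9 ± 4.45 in naive CD4 T.

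Of 13946 genes tested, 5285 were higher and 4693 lower in pDC than in the mean of the lymphocytes, 2874 and 1838 of them by at least 2-fold (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05). Within the identifier prefix of pDC, against the T cells alone, 5555 were higher and 5031 lower. With library size alone 4879 were higher and 5270 lower, 48.1% higher against 53%. The deposited log2 RPKM, which changes the scaling, the test and the genes tested together, gave 4521 higher and 6681 lower, 40.4% higher, and the median over all genes lay 0.18 lower on the log2 scale (-0.175).

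Each pairwise part asked whether a gene set pDC apart from every other type. Against naive CD4 T, 5336 genes were higher and 4808 lower in pDC, against naive CD8 T 5309 and 4787, and against peritoneal B 4650 and 4880 (edgeR adjusted p under 0.05). On the deposited log2 RPKM these were 4372 and 6512 against naive CD4 T and 4357 and 6427 against naive CD8 T. In all 3 parts 3123 genes were higher and 2404 lower, 1584 and 865 of them by at least 2-fold in each. The shared numbers were 2851 and 2751 with library size alone, and 2627 and 2954 on the deposited log2 RPKM, where more were lower than higher. Independent lists of these sizes would share 677.3 and 577.5 genes, and simulated unchanged groups shared at most 0 and 1 over 20 simulations. Those simulations left few calls to share, with at most 11 genes called in any part. Naive CD4 T and naive CD8 T resembled each other (r 0.9749 to 0.9756), so their parts are not independent. With 2 pDC libraries the shared side could not be split, so part of the excess may come from the shared libraries. Bst2 was higher by log2 4.67 (SE 0.1) than in naive CD4 T, 4.44 (SE 0.099) than in naive CD8 T and 4.90 (SE 0.1) than in peritoneal B. Tlr7 was higher by 4.91, 3.89 and 1.74, Irf7 by 2.12, 1.87 and 5.15, and Cxcr3 by 6.82, 3.29 and 4.94, in the same order. For Cxcr3 the first was 7.79 without naive CD4 T replicate 2, and the second 4.29 without naive CD8 T replicate 1 and 2.68 without naive CD8 T replicate 2. Cxcl10 was higher than in naive CD4 T (2.17, adjusted p = 0.0357) and peritoneal B (3.23, adjusted p = 0.00663) and not than in naive CD8 T. Its call against naive CD4 T was lost without naive CD4 T replicate 2 (1.18), naive CD8 T replicate 1 (2.17), naive CD8 T replicate 2 (2.17) or pDC replicate 1 (1.59), with DESeq2 (2.22) and on the deposited log2 RPKM (1.89), and kept without naive CD4 T replicate 1 (adjusted p = 0.00496), which left that group with no count. That against peritoneal B was lost without pDC replicate 1 (2.65) and on the deposited log2 RPKM (3.34), and kept without peritoneal B replicate 1 (4.40) and replicate 2 (2.59). Cd4, Cd8a and Cd19 in pDC were below the group sorted on them, by log2 -0.96, -2.64 and -8.14, and the call of Cd4 was lost on the deposited log2 RPKM (-1.11).

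The second comparison, peritoneal B against the mean of the T cells, set the B lineage and the lavage against the T lineage. Ms4a1 (chromosome 19, 11249679 to 11266149), which encodes the B cell protein CD20, had 2680 ± 218 CPM in peritoneal B and at most 0.0651 ± 0.00361 in T cells (edgeR quasi-likelihood, adjusted p = 1.17e-13). Syk, a kinase of the B cell receptor pathway, had 2320 ± 123 CPM and was at least 23800-fold higher than in naive CD8 T. Mzb1 (chromosome 18, 35647265 to 35650266), a chaperone of immunoglobulin assembly, had 444 ± 16 CPM, Cacna1e, a calcium channel, 526 ± 21.3 CPM and Diras2, a small GTPase, 360 ± 29.1 CPM. None had a count in T cells, so they were at least 4310-fold, 5120-fold and 3500-fold higher than in naive CD4 T. Lowest against the T cells were Tmie, a protein of hair cell channels with 66.4 ± 6.48 and 73.9 ± 2.13 CPM in T cells and 0.022 ± 0.0311 in peritoneal B, Dapl1, Slc16a5, Kcna2, Spsb1 and Tdrp. Of the B cell identity list, 22 of 23 rose and Cd72 did not pass (camera adjusted p = 1.92e-09, adjusted p = 0.279 with an estimated correlation). Blk, a kinase, rose to 794 ± 59.6 CPM. Of the T cell identity list, 23 of 24 fell and Cd2, an adhesion receptor, rose (camera adjusted p = 2.85e-10, adjusted p = 0.398 with an estimated correlation). Trac, a receptor constant gene, fell to 1.75 ± 0.633 CPM from 948 ± 14. Of the CD8 lineage list 16 of 22 fell (camera adjusted p = 3.73e-06, adjusted p = 0.279 with an estimated correlation). Of the CD4 lineage list 12 of 13 fell and Zbtb7b rose (camera adjusted p = 7.8e-05, adjusted p = 0.398 with an estimated correlation).

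The lists of antigen presentation, B-1 cells and secretion rose in peritoneal B. All 15 genes of the MHC class II list rose (camera adjusted p = 1.13e-07, adjusted p = 0.254 with an estimated correlation). Cd74, the invariant chain, had 11100 ± 478 CPM against 3.05 ± 0.111 in naive CD4 T (log2 fold change 11.86, SE 0.09, edgeR adjusted p = 1.17e-13). Of the B-1 cell list 12 of 14 rose and Cd5 and Spn fell (camera adjusted p = 0.00115, adjusted p = 0.432 with an estimated correlation). No other B cells were measured, so genes of B-1 cells are not told apart from genes of B cells in general. Bhlhe41, a transcription factor, had 102 ± 7.42 CPM and no count in T cells, and Zbtb32, another, had 386 ± 54.9 CPM against 0.859 ± 0.349 in naive CD4 T. All 7 plasma cell genes tested (of 8 listed) rose, such as Jchain with 27.7 ± 10.4 CPM (camera adjusted p = 0.000552, adjusted p = 0.322 with an estimated correlation). Of the list of the endoplasmic reticulum and secretion 23 of 30 rose and Dnajc3 and Edem1 fell (camera adjusted p = 0.0013, adjusted p = 0.435 with an estimated correlation). Pdia4, a disulphide isomerase, had 513 ± 62.8 CPM. Of the endosomal Toll-like receptor list 14 of 20 rose and Irf7, Pld3, Myd88, Traf6 and Ctsl fell (camera adjusted p = 0.022, adjusted p = 0.432 with an estimated correlation). Unc93b1, which carries the receptors to endosomes, had 831 ± 8.28 CPM against 4.93 ± 0.139 in naive CD4 T, and Tlr7 rose by log2 2.67 (SE 0.07, edgeR adjusted p = 1.32e-10). Cxcr3 (log2 0.12, edgeR adjusted p = 0.844) did not pass, nor did Cxcl10 (-2.15, edgeR adjusted p = 0.0534), which passed without naive CD4 T replicate 2 (-2.64, adjusted p = 0.00914), with the replicate number as a block (-2.18, adjusted p = 0.0349) and with library size alone (-2.21, adjusted p = 0.0484). Without naive CD4 T replicate 1, which left that group with no count, the direction turned (adjusted p = 0.65). It was -3.32 without peritoneal B replicate 1 and -1.51 without peritoneal B replicate 2.

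Interferon-stimulated genes were mostly lower in peritoneal B than in T cells. Of the list, 26 of 34 fell (27 adjusted over the list alone) and 6 rose (camera adjusted p = 7.88e-05, adjusted p = 0.398 with an estimated correlation). Irf7 fell by 3.16 on the log2 scale (SE 0.08, edgeR adjusted p = 7.79e-11), to 12.1 ± 1.39 CPM. Usp18, which restrains interferon signalling, had 2.95 ± 0.176 CPM against 29.5 ± 1.56 in naive CD4 T, and Ifit1, which binds viral RNA, 3.07 ± 0.548 against 40 ± 4.5. Ifitm3 and Stat2 were among those that rose, Stat2 to 164 ± 20 CPM from 99.9 ± 0.338. The pDC identity list was split, with 16 of 28 higher and 9 lower, and was not called (camera adjusted p = 0.215). Spib, a transcription factor, had 1050 ± 102 CPM in peritoneal B and 1010 ± 2.06 in pDC, while Cd7 and Atp1b1 were among those that fell. Not called either were the other pattern recognition receptors (14 higher, 5 lower of 21, camera adjusted p = 0.181), the chemokine receptors (11 higher, 5 lower of 19, camera adjusted p = 0.341), the regulatory T cell list (4 higher, 6 lower of 10, camera adjusted p = 0.5) and the immediate early list (9 higher, 10 lower of 22, camera adjusted p = 0.865, median log2 fold change -0.41 and mean 0.29). Tlr4, the sensor of lipopolysaccharide, rose to 32.2 ± 3.5 CPM, Cxcr5, a receptor for entry to B cell follicles, to 1060 ± 48.9 CPM, and Capg, an actin capping protein, to 614 ± 13.4 CPM. The cytokine list (8 higher, 5 lower of 18, camera adjusted p = 0.534) had a median of 0.041 that was -0.015 with library size alone and -0.23 on the deposited log2 RPKM, where 7 of 27 rose and 3 fell. Il12a had 13.9 ± 2.27 CPM in peritoneal B, at least 135-fold higher than in naive CD4 T. Tnf, Tnfsf10, Lta, Il16 and Ltb fell, the last with a log2 fold change of -0.27 that lost its call without naive CD4 T replicate 1 (-0.24), naive CD8 T replicate 2 (-0.26) or peritoneal B replicate 2 (-0.09). Ltb (-0.32, limma-trend adjusted p = 0.0512) and Lta (adjusted p = 0.105) were not called on the deposited log2 RPKM.

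Some genes of other cell types and of cell division were unequal between the 2 peritoneal B libraries. All 19 macrophage and monocyte genes tested rose (camera adjusted p = 3.79e-07, adjusted p = 0.322 with an estimated correlation). Lyz2, lysozyme, had 721 ± 383 CPM, with 992 in replicate 1 and 450 in replicate 2, and Fn1, fibronectin, 689 ± 239 CPM. All 6 neutrophil genes tested (of 13 listed) rose (camera adjusted p = 0.0312, adjusted p = 0.573 with an estimated correlation), with S100a9 at 17.2 ± 17.3 CPM. S100a8 and S100a9, with at most 3 counts in a T cell library, passed the filter through pDC and peritoneal B. The count and the camera result of this list were thus partly set by the filter. Without peritoneal B replicate 2 or any one of the T cell and pDC libraries, more genes of that list entered the test. A gene held by 1 library could then enter. The neutrophil genes Ngp and Ltf, not among those tested above, had 369 and 192 counts in peritoneal B replicate 1 and 3 and 0 in replicate 2. Of the cell cycle list 22 of 27 rose and Mcm4 and Mcm2 fell (camera adjusted p = 0.0118, adjusted p = 0.797 with an estimated correlation). Mki67, a marker of dividing cells, rose to 154 ± 140 CPM, with 55.3 in replicate 1 and 253 in replicate 2. On the deposited log2 RPKM 15 rose and 1 fell. Mcm4 and Mcm2 lost their calls without naive CD4 T replicate 1 (log2 fold change -0.28 and -0.30), naive CD4 T replicate 2 (-0.30 and -0.32), naive CD8 T replicate 1 (-0.21 and -0.27) or peritoneal B replicate 1 (-0.15 and -0.09), and Mcm4 on the deposited log2 RPKM (-0.37). Of the conventional dendritic cell list 9 of 13 rose and Id2 fell (2 of 15 fell on the deposited log2 RPKM, camera adjusted p = 0.022, adjusted p = 0.432 with an estimated correlation), with Wdfy4, a protein of antigen cross-presentation, at 1590 ± 119 CPM. The natural killer list (1 lower of 5, Prf1, camera adjusted p = 0.56), the platelet list (2 higher, 1 lower of 4, camera adjusted p = 0.503, Pf4 at 15.7 ± 5.7 CPM) and the erythroid list (2 higher of 4, camera adjusted p = 0.799) were not called. The erythroid genes were Hba-a2 and Hbb-bs at 3.3 ± 3.59 and 1.98 ± 1.92 CPM, and without peritoneal B replicate 1 none of 4 was called (log2 fold change 1.68 and 1.35). Hbb-bs also lost its call without naive CD4 T replicate 1 (2.81), and both did on the deposited log2 RPKM (2.71 and 2.17). There the erythroid median of 1.6 was -0.295, 2 of 9 natural killer genes fell, and 2 of 5 platelet genes rose and 2 fell. In total 5549 genes were higher and 4671 lower in peritoneal B, 3042 and 1802 by at least 2-fold (edgeR adjusted p under 0.05), 54.3% higher. With library size alone 5203 were higher and 5075 lower, 50.6% higher, and with the deposited log2 RPKM 4330 were higher and 6527 lower, 39.9% higher. Tissue and identifier prefix differed with the cell type.

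**Figure D2:**
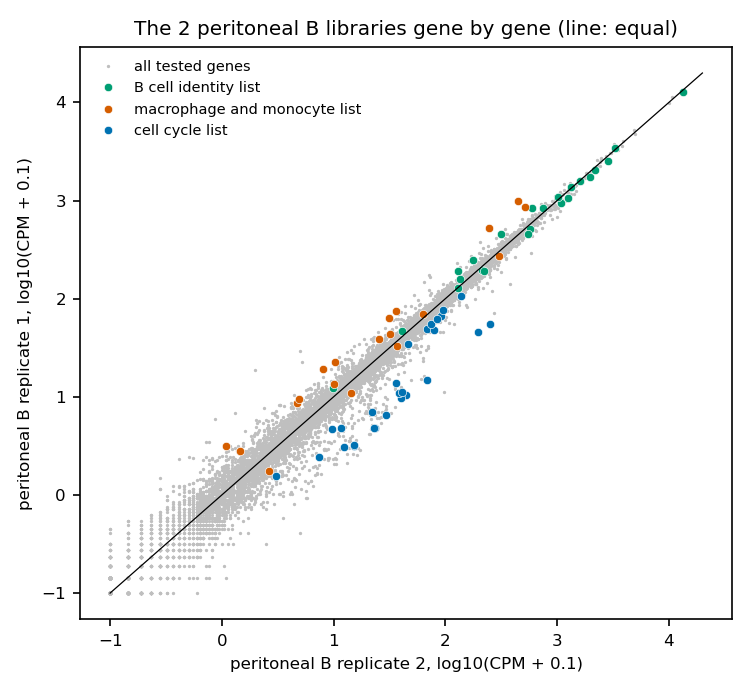
Level of each gene in peritoneal B replicate 2 (horizontal axis) and replicate 1 (vertical axis), as log10 of CPM plus 0.1. Genes of 3 lists are coloured, and the line marks equal levels. Macrophage and monocyte genes, 15 of 19, such as Lyz2 (992 and 450 CPM) lay towards replicate 1, cell cycle genes such as Mki67 (55.3 and 253 CPM) towards replicate 2, and B cell identity genes along the line.

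The third comparison, naive CD8 T against naive CD4 T, set the T lineages against each other within the same tissues and identifier prefix. The pDC and peritoneal B libraries are not compared in it and act on it only through the shared spread, the scaling and the filter. Besides the sort genes, Itgae (chromosome 11, 73090505 to 73147449), an integrin chain that binds epithelium, had 386 ± 36.6 CPM in naive CD8 T and 1.41 ± 0.161 in naive CD4 T (log2 fold change 8.09, SE 0.13, edgeR quasi-likelihood, adjusted p = 1.48e-10). Nkg7, a protein of cytotoxic granules, had 283 ± 22 CPM against 1.81 ± 0.61 (7.28, SE 0.17, edgeR adjusted p = 1.78e-09), and Plac8, Slc6a19 and Adgrg5 were also among the highest. Zbtb7b (chromosome 3, 89377644 to 89393673), the transcription factor of the CD4 lineage, had 298 ± 16.7 CPM in naive CD4 T and 0.133 ± 0.0993 in naive CD8 T (-11.08, SE 0.18, edgeR adjusted p = 1.48e-10, -12.06 without naive CD8 T replicate 1 and -10.47 without naive CD8 T replicate 2). Cd40lg, the ligand by which CD4 T cells help B cells, had 134 ± 5.96 CPM against 0.531 ± 0.397, St8sia6 131 ± 11.9 against 2.06 ± 0.436, and Myo10, a myosin, 50.2 ± 8.6 against 1.09 ± 0.566. Ly6c1 was lower in naive CD8 T (0.56 ± 0.261 CPM against 109 ± 1.51) and Ly6c2 higher (123 ± 49.1 against 2.85 ± 0.274), but these neighbours are nearly identical and their reads uncertain. Of the CD8 lineage list 18 of 22 rose and Fasl fell (camera adjusted p = 2.98e-11, adjusted p = 0.179 with an estimated correlation). Of the CD4 lineage list 9 of 13 fell (10 adjusted over the list alone, camera adjusted p = 1.68e-07, adjusted p = 0.322 with an estimated correlation). Both lists hold genes of the sort. Of the pDC identity list 9 of 28 rose (10 adjusted over the list alone) and 4 fell (camera adjusted p = 0.00161, adjusted p = 0.322 with an estimated correlation). Ccr9, a receptor for entry to the gut, had 255 ± 0.891 CPM in naive CD8 T and 6.13 ± 0.949 in naive CD4 T. On the deposited log2 RPKM 10 rose and 2 fell. Of the 4 that fell, Atp1b1 kept its call without each library. Lag3 (log2 fold change -1.83) lost it without naive CD4 T replicate 1 (-1.33), naive CD4 T replicate 2 (-2.21), naive CD8 T replicate 2 (-1.15), pDC replicate 1 (-1.83) and pDC replicate 2 (-1.83), and kept it without naive CD8 T replicate 1 (-3.01). It also lost it with the replicate number as a block (adjusted p = 0.0512), with limma-voom (adjusted p = 0.0742) and on the deposited log2 RPKM (adjusted p = 0.122). Lair1 lost it without naive CD4 T replicate 2 (-0.45) and naive CD8 T replicate 2 (-0.40) and on the deposited log2 RPKM (-0.59), and Tcf4 with limma-voom (-0.85) and without naive CD4 T replicate 2 (-0.55), naive CD8 T replicate 1 (-0.80) and naive CD8 T replicate 2 (-0.97).

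Among the focus genes, Tlr7 was higher in naive CD8 T (log2 fold change 1.02, SE 0.11, edgeR adjusted p = 9.46e-05) and so was Cxcr3 (3.53, SE 0.62, edgeR adjusted p = 0.0029). Cxcr3 had 12.2 CPM in naive CD8 T replicate 1 and 4 in replicate 2, and its log2 fold change was 2.53 without naive CD8 T replicate 1, 4.14 without naive CD8 T replicate 2 and 4.50 without naive CD4 T replicate 2. Replicate 1 also held more Cd44 (15.2 and 1.69 CPM), Ly6c2 (157 and 87.9) and Eomes (52.8 and 27.5), the last chosen after its values were seen. Tlr9 was at 2 counts or fewer in each group. Irf7 was called higher (0.25, SE 0.07, edgeR adjusted p = 0.0327), and the call was lost without naive CD4 T replicate 1 (0.22), naive CD4 T replicate 2 (0.29), naive CD8 T replicate 1 (0.27), naive CD8 T replicate 2 (0.25), pDC replicate 1 (0.25) or pDC replicate 2 (0.26), and on the deposited log2 RPKM (0.28). Cxcl10 did not pass (2.17, edgeR adjusted p = 0.102), but passed without naive CD4 T replicate 1 (adjusted p = 0.0289), which left that group with no count, and was at 1.18 without naive CD4 T replicate 2. Of the interferon-stimulated list 10 of 34 rose (14 adjusted over the list alone) and 3 fell (camera adjusted p = 0.0044, adjusted p = 0.435 with an estimated correlation). Mx1, an antiviral GTPase, had 16.8 ± 2.17 CPM against 2.54 ± 0.416 (2.72, SE 0.28, edgeR adjusted p = 7.61e-05), and Oas3, an RNA sensor, 101 ± 15.4 against 42.6 ± 1.95. Ifit2 fell (-0.92, SE 0.09, edgeR adjusted p = 8.2e-05), as did Ifi44 (-1.76) and Oas2 (-0.75). Without naive CD4 T replicate 1 the list count was 7 and 1, without naive CD4 T replicate 2 or naive CD8 T replicate 1 it was 5 and 2, without naive CD8 T replicate 2 it was 6 and 1, and on the deposited log2 RPKM it was 5 and 1. Ifi44 lost its call without naive CD4 T replicate 1 (-1.41) and naive CD8 T replicate 2 (-1.28) and was at -2.43 without naive CD8 T replicate 1, and Oas2 lost it without naive CD4 T replicate 1 (-0.76), naive CD4 T replicate 2 (-0.74), naive CD8 T replicate 1 (-0.76) and naive CD8 T replicate 2 (-0.73). Neither Ifi44 (-1.59) nor Oas2 (-0.80) was called on the deposited log2 RPKM.

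The immediate early and regulatory T cell lists were called lower in naive CD8 T, and the T cell identity list was not called. Of the last 8 of 24 fell and Themis rose (2 rose adjusted over the list alone, camera adjusted p = 0.19), with Cd28, a costimulatory receptor, at 147 ± 10.9 CPM against 409 ± 0.301 (log2 fold change -1.48, SE 0.13, edgeR adjusted p = 2.43e-05) and Cd5, which damps receptor signals, at 226 ± 25.3 against 543 ± 10.5. The call of Cd28 was lost on the deposited log2 RPKM (-1.57, limma-trend adjusted p = 0.219), where 0 of the list rose and 1 fell. The number that rose was 2 with library size alone and with the replicate number as a block, and 0 with DESeq2 size factors. Themis (0.46) lost its call without each T cell and each pDC replicate (0.38 without naive CD8 T replicate 1 to 0.54 without naive CD8 T replicate 2), with DESeq2 and with its size factors (0.45 with each), and on the deposited log2 RPKM (0.52). The list count was 5 lower without naive CD4 T replicate 1 and without naive CD8 T replicate 2, and the list was called without peritoneal B replicate 1 (adjusted p = 0.0428) and replicate 2 (adjusted p = 0.0449). Of the immediate early list 9 of 22 fell (13 adjusted over the list alone) and Ier3 rose (camera adjusted p = 0.00356, adjusted p = 0.435 with an estimated correlation), with 4 lower without naive CD4 T replicate 2 or naive CD8 T replicate 2 and 5 without naive CD8 T replicate 1. On the deposited log2 RPKM 1 of 23 rose and 2 fell. Nr4a1, a nuclear receptor induced by receptor signals, had 12.9 ± 1.21 CPM against 52.2 ± 5.58 (-2.01, SE 0.12, edgeR adjusted p = 1.77e-06). Hspa1a and Hspa1b, near-identical heat shock genes, were lower too, and Hspa1b, at 19.9 ± 16.6 CPM against 161 ± 87.8, lost its call without naive CD4 T replicate 1 (-2.30) and naive CD8 T replicate 1 (-2.35), and was at -4.29 without naive CD8 T replicate 2. Both lost it on the deposited log2 RPKM (-3.84 and -3.32). Of the regulatory T cell list 5 of 10 fell (7 adjusted over the list alone) and Ikzf2 rose (camera adjusted p = 0.00115, adjusted p = 0.398 with an estimated correlation), with Foxp3, the transcription factor of these cells, at 1.63 ± 0.0903 CPM against 7.86 ± 2.46. Without naive CD8 T replicate 1 the count was 3 of 11, and Ikzf2 (0.82) lost its call without it (0.71), without naive CD4 T replicate 2 (0.52) and on the deposited log2 RPKM (0.70), where 4 of 11 fell.

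The lists of chemokine receptors and conventional dendritic cells were called between the T lineages. Of the chemokine receptor list 5 of 19 rose and Ccr8 and Cxcr1 fell (camera adjusted p = 0.0285, adjusted p = 0.432 with an estimated correlation, and adjusted p = 0.193 without naive CD8 T replicate 1). Cxcr6, a receptor of tissue T cells, had 158 ± 9.14 CPM against 2.3 ± 0.12 (log2 fold change 6.10, SE 0.13, edgeR adjusted p = 7.08e-10). Of the conventional dendritic cell list Dpp4, Id2 and Xcr1 rose, 3 of 13 (camera adjusted p = 0.0223, adjusted p = 0.432 with an estimated correlation, and adjusted p = 0.0535 without naive CD8 T replicate 1), Dpp4, a peptidase, to 302 ± 3.95 CPM from 83.4 ± 2.7. The lists not called were the endosomal Toll-like receptors (6 higher and 3 lower of 20, 7 and 3 adjusted over the list alone, camera adjusted p = 0.384, median 0.094 and mean -0.0047), other pattern recognition receptors (6 and 1 of 21, 6 and 2 adjusted over the list alone, camera adjusted p = 0.162), MHC class II (4 and 1 of 15, camera adjusted p = 0.217), B-1 cells (3 and 4 of 14, camera adjusted p = 0.421, median -0.12 and mean 0.079) and the natural killer list (1 of 5, Prf1, camera adjusted p = 0.277). Lgmn, a lysosomal protease, had 0.721 ± 0.224 CPM against 20.4 ± 1.83, and Tlr12, a sensor of protozoan profilin, 42.9 ± 0.101 against 7.3 ± 0.518. H2-Oa, which regulates class II loading, had 26.1 ± 3.98 CPM against 3.84 ± 0.625. Prf1, perforin, lost its call (0.62) without naive CD4 T replicate 2 (0.49) and naive CD8 T replicate 1 (0.56) and on the deposited log2 RPKM (0.66), where the natural killer list's median of 0.619 was -0.214. Of the macrophage list Itgam fell, 1 of 19 (camera adjusted p = 0.5, median 0 and mean -0.57), and no gene of the neutrophil (camera adjusted p = 0.656), erythroid (0.481) or platelet list (0.654) was called, where the highest members were Gp1ba at 3.87 ± 0.261 CPM in naive CD8 T and Itga2b in naive CD4 T.

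Some list results between the T lineages changed when 1 library was left out. Where that library was of pDC or peritoneal B, the change came through the shared spread, the scaling or the filter, not through T cell values. The B cell identity list (4 higher and 2 lower of 23, camera adjusted p = 0.0749) was called without naive CD4 T replicate 1 (adjusted p = 0.00863) and without naive CD8 T replicate 2 (adjusted p = 0.0195). Cd79b, a chain of the B cell receptor, had 23.6 ± 1.86 CPM in naive CD8 T against 0.719 ± 0.137 in naive CD4 T (log2 fold change 5.02, SE 0.16, edgeR adjusted p = 1.64e-08). The plasma cell list (3 lower of 7, camera adjusted p = 0.0807) was called without naive CD8 T replicate 1 (adjusted p = 0.0172), and 1 gene was lower without naive CD4 T replicate 1 or naive CD8 T replicate 2. Prdm1, a transcription factor, was lower throughout (2.71 ± 0.472 CPM against 10.4 ± 0.417). The cell cycle list (Ccne1 and Mcm6 higher of 27, camera adjusted p = 0.109) was called without naive CD8 T replicate 2 (adjusted p = 0.0303), peritoneal B replicate 1 (adjusted p = 0.0045) or peritoneal B replicate 2 (adjusted p = 0.00467), with 6 higher in the last pair. Mcm6 (0.47) lost its call without naive CD4 T replicate 1 (0.47), naive CD4 T replicate 2 (0.47) and naive CD8 T replicate 1 (0.37) and on the deposited log2 RPKM (0.50), where 1 gene of the list rose. The cytokine list (1 higher and 4 lower of 18, camera adjusted p = 0.68) had 1 and 1 without naive CD4 T replicate 1, 0 and 1 without naive CD4 T replicate 2 or naive CD8 T replicate 2, 0 and 3 without naive CD8 T replicate 1, and 0 and 2 of 27 on the deposited log2 RPKM. Tnf was at 8.72 ± 0.573 CPM against 25.4 ± 1.75 (-1.54, SE 0.19, edgeR adjusted p = 0.000327). The list of the endoplasmic reticulum and secretion (3 higher and 1 lower of 30, 2 and 1 adjusted over the list alone, camera adjusted p = 0.69) had 2 and 0 without naive CD4 T replicate 1, 1 and 0 without naive CD8 T replicate 2, and 2 and 2 with the replicate number as a block. Sec11c, of the signal peptidase, rose to 69.4 ± 2.71 CPM from 39.5 ± 3.79.

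Between the T lineages 1246 genes were higher and 1320 lower in naive CD8 T, 2566 in all, 436 and 426 of them by at least 2-fold (edgeR adjusted p under 0.05). The number was 1574 without naive CD4 T replicate 1, 1548 without naive CD4 T replicate 2, 1614 without naive CD8 T replicate 1 and 1561 without naive CD8 T replicate 2. Data simulated for this comparison had the same limits as those for pDC. On them the test recovered 62.1% of genes changed 1.5-fold, 78.1% of those changed 2-fold and 96.2% of those changed 4-fold. Of its calls 8.11% were false, above the nominal 5%.

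**Figure D3:**
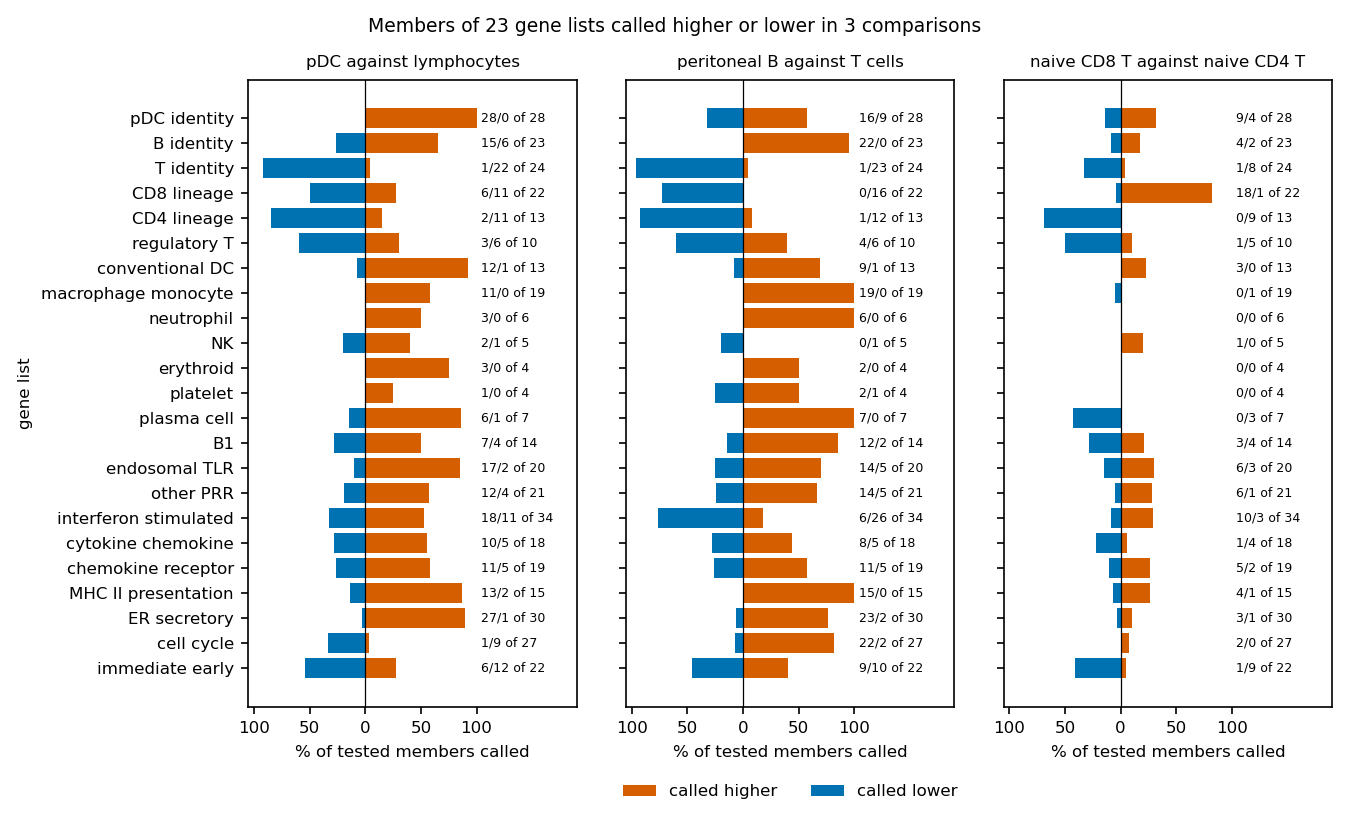
Percent of the tested genes of each of 23 lists called higher (to the right) or lower (to the left) in the 3 comparisons, with the numbers of genes beside the bars. All 28 pDC identity genes were higher in pDC, all 15 MHC class II genes were higher in peritoneal B than in T cells, and 18 of 22 CD8 lineage genes were higher in naive CD8 T than in naive CD4 T.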

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

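Fits of the named genes on the deposited log2 RPKM, and counts of called list genes under other scalings and without single peritoneal B libraries, were chosen after seeing the data, and the other alternatives before. Over the 6 comparisons, the genes shared by the pairwise parts and the gene lists as a whole, 130 values under an alternative stayed within 1.5 times of the value reported, 13 were lower and 1 was higher.

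The test against a 2-fold change (glmTreat) asks for a larger effect and called fewer genes by construction: 3875 in pDC against lymphocytes, 4498 in pDC against naive CD4 T, 4424 in pDC against naive CD8 T, 3694 in pDC against peritoneal B, 4061 in peritoneal B against T cells and 361 in naive CD8 T against naive CD4 T, with 1856 shared by the pairwise parts. At an adjusted p under 0.01, 1453 genes were called between naive CD8 T and naive CD4 T in place of 2566. Leaving out 1 library gave between 1548 and 2981 genes in that comparison, the lowest without naive CD4 T replicate 2, next to 1574 without naive CD4 T replicate 1, 1614 without naive CD8 T replicate 1 and 1561 without naive CD8 T replicate 2. A group then has 1 library, which is assumed to vary like those of the other groups. Fitted with the 2 T cell groups alone, naive CD8 T against naive CD4 T had 2993 called of 11908 tested. DESeq2 called 1865 genes there, and 9010 in pDC against lymphocytes in place of 9978. Of the 5527 genes shared by the pairwise parts, 4516 remained with DESeq2.

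Of the 69 pairs of list and comparison, 31 were called by camera with the preset correlation, 0 with an estimated correlation and 50 by fry. Fry asks another question, whether the genes of a list move on balance one way, and does not compare them with other genes. In single pairs, 765 values under an alternative stayed on the same side of the threshold, 36 lost a call and 25 gained one in the same direction. In 2 pairs that camera did not call, fry called the list in the other direction: the platelet list in pDC against lymphocytes (camera towards lower, adjusted p = 0.706, fry towards higher, adjusted p = 0.00894) and the regulatory T cell list in peritoneal B against T cells (0.5 and 0.00225). The macrophage and monocyte list in pDC against lymphocytes (adjusted p = 0.0393) lost its call without pDC replicate 1 (0.0589) and without peritoneal B replicate 2 (0.0507), and the cause was not tested. Among the values of named genes under an alternative, 3014 stayed on the same side of the threshold, 115 lost a call and 5 gained one. In 1 more, called in 1 of the 2 fits compared, the sign changed. That one was Mx1 in peritoneal B against T cells, not named in the report for this comparison. Its log2 fold change was 0.52 (edgeR adjusted p = 0.0468), and -0.17 on the deposited log2 RPKM (limma-trend adjusted p = 0.566). Sign changes of genes called in neither fit were counted as staying. Without naive CD4 T replicate 1, Cxcl10 in peritoneal B against T cells went from -2.15 to 0.39. Tlr9 in naive CD8 T against naive CD4 T then went from -0.93 to 2.45.

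Pairing of the samples by replicate number was not seen in the values, which cannot exclude shared animals or sort days. Libraries with the same number in different groups did not deviate together, with correlations of their deviations, across genes, from -0.0402 to 0.0254. With the replicate number as a block 10008 genes were called in pDC against lymphocytes, 10164, 10114 and 9543 in its pairwise parts, 10222 in peritoneal B against T cells and 2624 in naive CD8 T against naive CD4 T, and 5452 of the shared genes remained. The block called 30 pairs of list and comparison, and the macrophage and monocyte list in pDC against lymphocytes then missed the threshold (0.0548). Of the named genes, the block ended the call of Lag3 in naive CD8 T against naive CD4 T (0.0512) and added that of Cxcl10 in peritoneal B against T cells (0.0349), and it changed no other call of a named gene or list.

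The deposited log2 RPKM, which changes the scaling, the test and the genes tested together, moved the balance of higher and lower calls. The median over all genes shifted by -0.243 on the log2 scale in pDC against naive CD4 T, -0.229 in pDC against naive CD8 T, -0.228 in peritoneal B against T cells and -0.0232 in pDC against peritoneal B. With library size alone it shifted by -0.101 in pDC against naive CD8 T. No gene in pDC against lymphocytes changed direction between calls with DESeq2 size factors, library size alone or limma-voom, and 4 did with the deposited log2 RPKM, as did 19 in peritoneal B against T cells. Depth limits Cxcl10, which had at most 22 counts in a library.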

Other observations

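The tests of explanations given here, and the families of receptor segments and ribosomal proteins, were chosen after the results were seen, while the gene lists and comparisons were not. Of 187 immunoglobulin V segments tested, 187 were higher in peritoneal B than in T cells, and 204 of 206 were on the deposited log2 RPKM. A segment without counts in T cells could pass the filter only through peritoneal B or pDC. The first number was thus set by the filter at least in part. Ighv11-2, a heavy chain segment, had 240 and 163 CPM in the 2 peritoneal B libraries and Ighv12-3 had 153 and 146, while neither had a count in T cells. Of these segments 102 were higher in pDC than in naive CD4 T (68 of 206 on the deposited log2 RPKM) and 185 lower than in peritoneal B. Igha, the constant gene of IgA, had 54.9 and 98.3 CPM in the pDC libraries and 6.41 and 6.24 in peritoneal B. Of 83 T cell receptor V segments, 7 were higher and 20 lower in naive CD8 T than in naive CD4 T. Trbv12-1 had 43 and 41.2 CPM in naive CD8 T against 10.2 and 11.6 in naive CD4 T, and Trbv31 had 13.2 and 11.6 against 51.6 and 52.3. Segments of 1 family resemble each other, so reads between them are uncertain.

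Ribosomal protein genes were lower in pDC. Of 81 tested, 74 were lower and 5 higher in pDC than in the mean of the lymphocytes, with a median log2 fold change of -1.12, and the median was -1.39 on the deposited log2 RPKM and -1.2 with library size alone. Rpl3 had 161 ± 14.1 CPM in pDC against 316 ± 9.88 in naive CD4 T (mean ± SD, n = 2). These genes have many pseudogenes. Gm2a, which encodes a lysosomal activator protein and is missing from the deposited log2 RPKM, had 1530 ± 147 CPM in pDC, against 337 ± 27.7 in peritoneal B and 137 ± 6.18 in naive CD4 T (log2 fold change 3.10 against lymphocytes, SE 0.07, edgeR adjusted p = 2.68e-11). Every library held both Xist, 378 to 1340 CPM, and the Y-linked Ddx3y, 39.1 to 124 CPM. Their proportion differed between the naive CD8 T libraries, with Xist at 584 and 1030 CPM and Ddx3y at 100 and 39.1. In pDC against lymphocytes Eif2s3y (edgeR adjusted p = 0.0179) and Uty (0.0333) were called, and Xist, Ddx3y and Kdm5d were not. In peritoneal B against T cells only Xist was called among these (0.00212). Sex was not a term of the model, so a difference in the mix of sexes was not separated from cell type. Lars2 differed between the naive CD8 T libraries, at 1050 and 200 CPM.

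Of the 19 macrophage genes tested, 15 were higher in peritoneal B replicate 1 than in replicate 2. The median log2 ratio over the list was 0.86 (quartiles 0.30 to 1.06, 1.82-fold), against -0.10 to 0.09 for the central 95% of 10000 random lists of matched level. Random lists were drawn gene by gene, so a list whose genes vary together can leave this range whatever the cause. RNA of peritoneal macrophages in the sort, which excluded F4/80 and Mac-1, is a candidate explanation, led in level by Lyz2 (992 and 450 CPM), Fn1 (857 and 520) and Apoe (522 and 244). Itgam (-0.15), Cd68 (-0.17), Ccr2 (-0.38) and Ms4a7 (-0.59) were lower in replicate 1 and Adgre1 was close to equal (0.16), and whether these have another source is open. The identifier prefix cannot be told apart from the cell type, since 0 libraries of another group have the prefix of the peritoneal B libraries. The T cell, neutrophil and erythroid lists were also higher in replicate 1 (median log2 ratios 0.71, 1.62 and 2.24), so the excess is not limited to macrophage genes. Also above their matched ranges were the CD8 lineage, cytokine and chemokine receptor lists (0.33, 0.35 and 0.33). Below theirs were the conventional dendritic cell, B-1 cell and interferon-stimulated lists (-0.31, -0.13 and -0.10) and the cell cycle list. Expression of the macrophage, T cell, neutrophil and erythroid genes by the B cells was not tested.

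The cell cycle list went the other way, with a median log2 ratio of replicate 1 to replicate 2 of -1.63 (quartiles -2.14 to -0.60), which is 3.1-fold higher in replicate 2. A difference in library size or scaling would move the B cell identity list alike, but its median ratio was 0.01 (quartiles -0.15 to 0.22). The cells that may have brought the macrophage RNA would move the list towards replicate 1, so they are argued against too. More dividing B cells in replicate 2 is open, and no biological explanation was tested, since the design gives the replicates no difference.

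The conventional dendritic cell list was higher in pDC than in lymphocytes, and conventional dendritic cells in the sort, which took CD11c low and CD45RA high cells, would bring their genes together. Of its 15 genes, 6 were under 5 CPM in both pDC libraries (at most 4.16 CPM), among them Xcr1 and Batf3, while Clec9a had 552 ± 31.4 CPM and Cd209a 637 ± 7.65. This argues against cells that express the whole list together as its source. The list was not divided by kind of conventional dendritic cell, so a kind with little of those 6 genes is not excluded. The identifier prefix is argued against by 10 genes that were higher in pDC than in both T cell groups of the same prefix. Reads shared between Cd209 paralogs were not tested, and expression of these genes by the sorted pDC is left as a hypothesis.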
